A study of Mus musculus with 9 samples.

How the data were processed

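Messenger RNA abundance was measured by RNA sequencing in 9 aortas of mice without a working Apoe gene, 3 on a chow diet (CD), 3 on a high fat diet (HFD) and 3 on a high fat diet with injections of an iron salt (HFD_IO). Per the labels' protocols, RNA was extracted with a Qiagen column kit and libraries were made with an NEBNext kit for Illumina. Strand information was not given in the sources used here, so an antisense gene cannot be told from its partner. The submitters' processing notes name HISAT2, and they name hg38, a human genome build. The gene identifiers in the table are mouse: 54409 of 54532 are in GENCODE M21, and 98.3% of those have the same chromosome, start and end as in that annotation of GRCm38. Coordinates below are those of the table, on that mouse build. The counting tool and annotation release are not given in the sources used here.

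The values are FPKM (fragments per kilobase of gene length, scaled for sequencing depth), deposited by the authors with 1 column per library and with the length of each gene. Columns carry a group name and a number that the sample labels do not repeat, so a library is named here by its column and was assigned only to its group. The product of FPKM and gene length was a whole multiple of 1 step in 100% of the values above 0 in every library, within 0.05 of a read. Whole reads per gene were therefore read back, and they sum to between 16660963 and 18308450 per library. The denominators implied by the deposited values were 0.895 to 1.104 times those sums. They were proportional to median-of-ratios size factors computed from the recovered reads, within 0.003% in every library, so the deposited values carry a scaling of that kind and not the plain library totals. At this depth 1 read in a gene of 1 kilobase is worth 0.0541 to 0.0615 FPKM.

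Fold changes and tests were computed from log2(FPKM + 1) for 13883 genes with an FPKM of at least 1 in at least 3 of the 9 libraries. The addition of 1 understates the change of weakly expressed genes. All 9 libraries entered 1 linear model with 3 group means, fitted with limma 3.58.1 in R 4.3.3 with a mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. The threshold was an adjusted p of 0.05. A moderated F test covered the 3 groups together. Gene lists were 42 sets of genes fixed before the data were examined, and 891 of their 892 entries were found in the table. They were tested with camera at a preset correlation of 0.01, and beside it with camera at an estimated correlation and with fry, which asks whether the members of a list move on balance in 1 direction. The lists were adjusted over the 42 lists of a comparison. The groups hold 3 libraries, so p-values of single genes, of the F test and of fry measure the spread between these aortas. Camera at the preset correlation compares the members of a list with the other genes and takes them as nearly independent. Its small p-values therefore do not measure that spread.

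The genes named were chosen by a rule fixed before the data were examined. In each comparison these are the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, without predicted genes, pseudogenes and immunoglobulin or T cell receptor segments. To these come up to 4 members with the largest absolute change in each list, and a fixed set of iron-related and atherosclerosis genes. Some genes that meet the rule are not reported here. A gene outside this rule is said to have been chosen after its values were seen. Counts at other settings were computed for other pseudocounts, filters, scalings, variance models, library weights, covariates and for leaving out each library. Voom on the recovered reads, removal of each library's trend on gene length and GC content, protein-coding genes alone, omission of both CD_1 and HFD_3, and list tests by fry after removal of the trends or with the adipocyte covariate, and by camera and fry with the skeletal muscle covariate, were chosen after seeing the data. GC content was taken from GENCODE M21 transcripts and was known for 99.9% of the tested genes.

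The calculations were tested on simulated data drawn from the real means and library sizes with 200 genes changed by known folds. In the HFD against CD simulation of 13784 tested genes, 100% of genes raised 4-fold, 60% of genes raised 2-fold and 2% of genes raised 1.5-fold were called, beside 0.15% of the unchanged genes. In the HFD_IO against HFD simulation of 13755 genes the shares were 100%, 56% and 6%, beside 0.09% of the unchanged genes. In the HFD_IO against CD simulation of 13735 genes they were 100%, 44% and 2%, beside 0.08%. Each gene was drawn independently with 1 fixed spread and without shifts shared across a library. These shares therefore check the calculation and do not give the share of false calls in the real data. Replicate libraries were compared by a chi-square of their recovered reads over genes, to look for a library deposited under 2 names, which would give a value near 1 per degree of freedom. The value was 6.41 for CD_2 against CD_3 and 26.19 to 56.43 for the other pairs within a group, so no pair agreed within sampling noise. Each library was counted as 1 sample because the labels list 9 aortas.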

Results

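The transcriptome of the aorta was compared between 3 groups of Apoe-deficient mice, which develop atherosclerosis because they lack apolipoprotein E, the ligand through which remnant particles are cleared. The animals were 6 to 8 weeks old at the start of a regimen of 24 weeks. The groups received chow (CD), a high fat diet (HFD), or a high fat diet with intraperitoneal ammonium iron(III) citrate (HFD_IO), with 3 aortas in each. The series asks, by its title, about iron overload in atherosclerosis. The recovered reads per library ranged from 16660963 to 18308450. Values are the deposited FPKM, given as mean ± SD with n = 3, and changes are log2 fold changes of FPKM + 1 with limma's standard error (SE) and adjusted p.

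Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188, GRCm38), the gene the genotype names as disrupted, was listed at 12.6 ± 1.82 FPKM in CD, 12.7 ± 2.71 in HFD and 19.4 ± 2.28 in HFD_IO. No library without the disruption was analysed here, and a value over the whole gene does not separate intact from truncated transcripts. The difference between HFD_IO and HFD (0.59, SE 0.17, adjusted p = 0.0279) was lost when any of 4 single libraries was left out, with adjusted p = 0.0564 without HFD_2, 0.0834 without HFD_3, 0.0647 without HFD_IO_1 and 0.0922 without HFD_IO_2, and with no filter on low values (0.065). The difference between HFD_IO and CD (0.58, SE 0.17, adjusted p = 0.0251) was lost without CD_2 (0.0662), CD_3 (0.0898), HFD_IO_1 (0.0532) or HFD_IO_2 (0.0957), after rescaling to TPM (0.186) and with no filter (0.0547).

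The first comparison asked what the high fat diet changed. Macrophage and lysosome genes rose, and endothelial genes fell. Spp1 (osteopontin, ENSMUSG00000029304, chromosome 5, 104435118 to 104441050, GRCm38), a secreted matrix protein of activated macrophages, was at 11.2 ± 2.26 FPKM in CD and 871 ± 130 in HFD, a log2 change of 6.17 (SE 0.25, adjusted p = 4.85e-06). Cd5l, Gpnmb, Mmp12, Lgals3 and Trem2, which are expressed by lipid-laden macrophages, rose by 3.83, 3.72, 3.59, 3.49 and 3.38. The cathepsin Ctss and the lysozyme gene Lyz2 rose by 3.40 and 3.34, and the remaining genes among the 10 largest rises under the naming rule were Ibsp, a bone matrix protein (4.19), and Npy, a neuropeptide (3.55). In all, 3030 genes rose and 2440 fell among 13883 tested, and 50.7% of the genes had groups that did not overlap, where chance gives 10%. Rescaling to TPM moved the median change of all genes to -0.30 and left 1018 genes higher and 4948 lower, and removal of length and GC trends gave 2035 higher and 2939 lower.

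Of 23 tested lipid-laden macrophage genes 21 rose, with a median of 1.91 (21 adjusted over the list alone; camera adjusted p = 3.85e-11, fry adjusted p = 0.000441, adjusted p = 0.497 with an estimated correlation). Of 24 macrophage markers 18 rose, among them Tyrobp and Clec7a (18 adjusted over the list alone; camera adjusted p = 3.24e-07, fry adjusted p = 0.000837, adjusted p = 0.55 with an estimated correlation). All 26 lysosome genes tested rose, by 2.57 for Ctsl, 2.28 for Ctsd and 2.21 for Ctsb (26 adjusted over the list alone; camera adjusted p = 4.58e-12, fry adjusted p = 0.000353, adjusted p = 0.497 with an estimated correlation). Of 27 cytokine, chemokine and adhesion genes 14 rose and 2 fell, with Cxcl13 at 3.07 and Ccl6 at 2.35 (16 and 3 adjusted over the list alone; camera adjusted p = 0.003, fry adjusted p = 0.0115, adjusted p = 0.665 with an estimated correlation).

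Genes of oxidative phosphorylation, antioxidant defence and glycolysis were also higher in HFD. Of 36 nuclear-encoded genes of oxidative phosphorylation 32 rose, with a median of 0.75, for example Uqcrq by 1.38 and Ndufa1 by 1.35 (35 adjusted over the list alone; camera adjusted p = 3.13e-09, fry adjusted p = 0.015, adjusted p = 0.711 with an estimated correlation). Of 29 genes listed as antioxidant enzymes or as targets of NRF2, the regulator of antioxidant defence, 19 rose, with Hmox1 at 2.03 and Gpx1 at 1.36 (20 adjusted over the list alone; camera adjusted p = 1.13e-05, fry adjusted p = 0.00938, adjusted p = 0.665 with an estimated correlation). Of 21 glycolysis genes 12 rose and 1 fell, with Hk3 at 2.21 and Pfkp at -1.09 (13 and 2 adjusted over the list alone; camera adjusted p = 0.00173, fry adjusted p = 0.000353, adjusted p = 0.497 with an estimated correlation). Fatty acid oxidation genes rose in 16 of 25 (19 adjusted over the list alone; camera adjusted p = 0.000122, fry adjusted p = 0.0517, adjusted p = 0.72 with an estimated correlation). Of 22 cholesterol synthesis genes 2 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.523, fry adjusted p = 0.639). Of 21 genes of fatty acid and triglyceride synthesis 2 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.669, fry adjusted p = 0.881). In these libraries short genes were higher and long genes lower in HFD: the median change was 0.41 in the shortest of 5 equal length classes of protein-coding genes and -0.21 in the longest. Fat markers moved the same way, with white adipocyte genes at a median of 0.87 (6 of 19 rose, also 6 adjusted over the list alone; camera adjusted p = 0.00381, and 0.0626 with an FPKM minimum of 5, fry adjusted p = 0.104, adjusted p = 0.835 with an estimated correlation) and, of 17 brown adipocyte genes, 9 that rose, Ucp1 by 2.10, and 3 that fell (9 and 3 adjusted over the list alone). The brown adipocyte list was not past the threshold (camera adjusted p = 0.145, fry adjusted p = 0.122). Nor were the skeletal muscle markers, at a median of 1.22 with 4 of 11 that rose and 1 that fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.215, fry adjusted p = 0.115). On the log2 scale the oxidative phosphorylation genes averaged 6.40, 6.51 and 7.03 in HFD_1, HFD_2 and HFD_3, and the white adipocyte markers 5.33, 5.28 and 6.24. The skeletal muscle markers averaged 2.03, 3.49 and 3.22, beside 1.79 to 2.10 in CD.

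Endothelial genes fell. Of 20 tested markers 16 fell and 1 rose, with a median of -0.87 (16 and 1 adjusted over the list alone; camera adjusted p = 3.94e-06, fry adjusted p = 0.0125, adjusted p = 0.665 with an estimated correlation). Ptprb, Tek, Pecam1 and Cdh5, which act at endothelial junctions or as endothelial receptors, fell by 2.00, 1.88, 1.51 and 1.46. The 10 largest falls were led by Slc25a34, a mitochondrial carrier, at 27.8 ± 1.68 FPKM in CD and 2.11 ± 0.0316 in HFD (fell by 3.21 on the log2 scale, SE 0.10, adjusted p = 1.75e-06), and held Wdr95, Tmem82, Npas4, Npas2 and Igsf9 beside the precursor genes Mir1898, Mir23a, Mir365-1 and Mir3058. These precursors are 75 to 91 bases long, so few reads set their FPKM. The call was lost for Mir23a without CD_2 (adjusted p = 0.0515) or HFD_2 (0.0523), and for Mir365-1 without CD_2 (0.062), CD_3 (0.0607) or HFD_3 (0.0565). At a pseudocount of 0.01 it was lost for Mir1898 (0.061), Mir23a (0.0556) and Mir3058 (0.0517). Circadian genes moved in both directions: Npas2 fell by 2.39, Arntl fell by 1.71 and Nr1d1 fell by 1.58, while Cry1 rose by 1.68. The circadian list had 8 members that rose and 4 that fell of 17 (10 and 4 adjusted over the list alone) and was not past the threshold for a shift in 1 direction (camera adjusted p = 0.475). Fry's mixed test, which counts changes in either direction, gave it an adjusted p of 1.04e-07. In this comparison 32 of the 42 lists passed the mixed test.

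Iron genes were described as a fixed set. Ftl1, the ferritin light chain, rose from 351 ± 23.0 to 1230 ± 237 FPKM, Fth1, the heavy chain, rose by 0.94 (adjusted p = 0.00955, beside a change of 0.24 with 0.415 after quantile normalization, and 0.94 with 0.552 with no filter on low values), and Tfrc, the transferrin receptor, rose by 1.11. Bmp6, which induces hepcidin, fell by 1.84. Slc40a1, the iron exporter ferroportin, was at 0.854 ± 0.0717 FPKM in CD and 1.72 ± 0.719 in HFD (adjusted p = 0.34). Lcn2, which binds iron-carrying siderophores, rose by 3.31, and Cp changed by -0.02 (adjusted p = 0.937). Gpx4, which reduces lipid peroxides, rose by 0.60 (adjusted p = 0.0215), a call lost without CD_2 (0.0796), CD_3 (0.0714), HFD_2 (0.0539) or HFD_3 (0.0687) and with no filter (0.0531). It was also lost after quantile normalization, which left a change of 0.09 (0.607), and after rescaling to TPM (0.20, with 0.266). Of 28 iron genes 11 rose and 3 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.17, fry adjusted p = 0.00347). Ferritin genes have many processed copies, so their reads may be shared among them.

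With the mean of the adipocyte markers as a covariate 1512 genes were past the threshold in HFD against CD, and with the skeletal muscle markers 1002, beside 5470 without. CD_1 lay apart from CD_2 and CD_3 on the third principal component (33.28 against -13.47 and -13.13). Other ways of splitting the 6 libraries into 3 and 3 gave 14 to 22 lists by camera, where the real split gave 16, and fry, counted over splits after the data were seen, gave 17 lists for the real split and 0 for each other split.

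**Figure D1:**
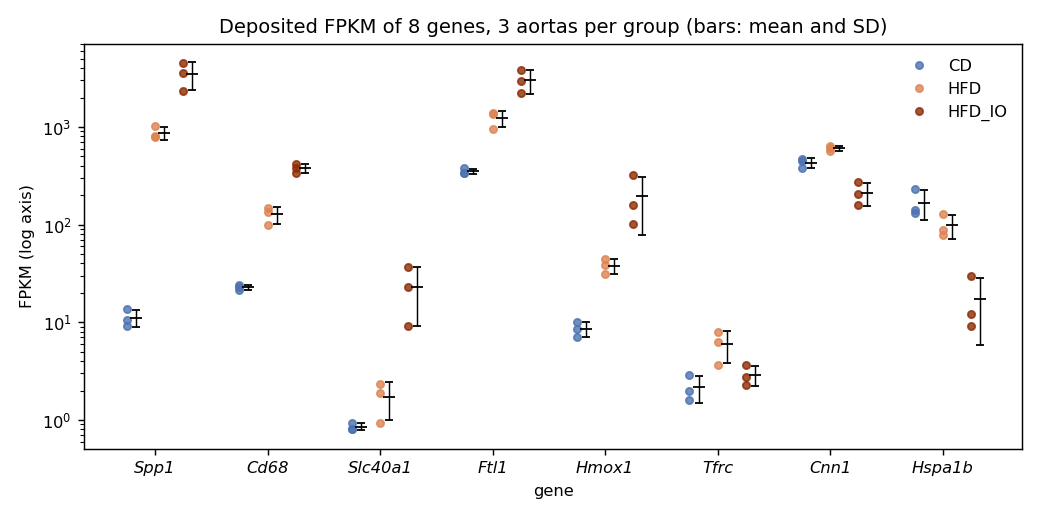
Deposited FPKM of 8 genes on a log axis, with a point for each of the 3 aortas per group and the mean and SD beside them. Spp1 averaged 11.2 in CD, 871 in HFD and 3480 in HFD_IO.

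The second comparison asked what iron added to the high fat diet. Macrophage and protease genes rose further, while contractile, heat shock and nuclear-encoded oxidative phosphorylation genes fell. Of 22 cartilage genes 10 rose, but that list was not past the threshold by fry. Mmp13, a collagenase (ENSMUSG00000050578, chromosome 9, 7272514 to 7283331, GRCm38), was at 1.58 ± 0.441 FPKM in HFD and 26.8 ± 9.10 in HFD_IO (3.40, SE 0.23, adjusted p = 0.000181). Slc40a1 (chromosome 1, 45908068 to 45926523) followed at 1.72 ± 0.719 and 23.1 ± 14.0 FPKM (2.99, SE 0.41, adjusted p = 0.0021). Grem1, Clec4d, Chad, Col10a1, Snorc, Ch25h and Adam8 were also among the 10 largest rises under the naming rule, between 2.21 and 2.85. In all, 1956 genes rose and 2013 fell, and 48.5% of genes had groups that did not overlap, where chance gives 10%. Rescaling to TPM moved the median change to 0.14 and left 2373 higher and 1160 lower.

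Of the iron-handling genes that changed, most rose. Ftl1 rose further to 3015 ± 821 FPKM (1.28, SE 0.23, adjusted p = 0.00539), Hmox1, which breaks down heme, rose from 38.1 ± 6.92 to 195 ± 116 (2.17, SE 0.36, adjusted p = 0.00394), and Slc11a1 and the ferroxidase Cp rose by 1.73 and 0.96. Fth1 was at 7228 ± 607 FPKM in HFD and 5755 ± 717 in HFD_IO (adjusted p = 0.271). Tfrc fell by 0.80 (adjusted p = 0.0408), a call lost without HFD_1 (0.113), HFD_2 (0.11), HFD_IO_1 (0.0525), HFD_IO_2 (0.099) or HFD_IO_3 (0.118), with no filter (0.105) and after rescaling to TPM (0.111). Lcn2 was at 22.5 ± 10.8 and 35.3 ± 17.5 FPKM (adjusted p = 0.246). Gpx4 fell by 0.59 (adjusted p = 0.0285), a call lost without HFD_2 (0.0669), HFD_3 (0.0954), HFD_IO_1 (0.0589), HFD_IO_2 (0.0635) or HFD_IO_3 (0.0854), with no filter (0.0729), and after quantile normalization, which left a change of -0.26 (0.165). Of 28 iron genes 9 rose and 1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0229, fry adjusted p = 0.00656, adjusted p = 0.49 with an estimated correlation). Hamp had at most 5 reads in any library and was not tested. Slc7a11, the cystine importer, was below the filter, at 2.32, 0.4 and 0.33 FPKM in the HFD_IO libraries and at most 0.168 in the other 6.

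Of 23 lipid-laden macrophage genes 18 rose, with Spp1 at 1.96, Mmp12 at 2.15 and Lpl at 1.78 (18 adjusted over the list alone; camera adjusted p = 3.62e-09, fry adjusted p = 0.00656, adjusted p = 0.49 with an estimated correlation). Of 24 macrophage markers 15 rose, with Cd68 from 128 ± 25.2 to 380 ± 41.1 FPKM and Adgre1 at 1.46 (16 rose and 1 fell adjusted over the list alone; camera adjusted p = 5.08e-06, fry adjusted p = 0.00656, adjusted p = 0.49 with an estimated correlation). Of 22 matrix proteases and inhibitors 13 rose and 2 fell (15 and 2 adjusted over the list alone; camera adjusted p = 1.67e-05, fry adjusted p = 0.000273, adjusted p = 0.218 with an estimated correlation). Lysosome genes rose in 15 of 26, with Gla at 1.10 (15 adjusted over the list alone; camera adjusted p = 8.43e-07, fry adjusted p = 0.00656, adjusted p = 0.49 with an estimated correlation). Of 27 cytokine, chemokine and adhesion genes 14 rose (16 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.67e-05, fry adjusted p = 0.00656, adjusted p = 0.49 with an estimated correlation). Among them the chemokines Ccl3, Ccl4 and Ccl2 rose by 1.98, 1.79 and 1.67. Cartilage genes rose in 10 of 22 (12 adjusted over the list alone; camera adjusted p = 0.000625, fry adjusted p = 0.0684, adjusted p = 0.656 with an estimated correlation).

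Contractile smooth muscle genes fell in 15 of 22, with a median of -0.99 (18 fell adjusted over the list alone; camera adjusted p = 2.59e-08, fry adjusted p = 0.00656, adjusted p = 0.49 with an estimated correlation). Cnn1, a calponin of differentiated smooth muscle, fell from 605 ± 37.1 to 213 ± 56.7 FPKM, and Des and Ppp1r14a fell by 1.49 and 1.46. Skeletal muscle markers moved with them, with a median of -1.21 (3 of 11 fell, and 9 adjusted over the list alone; camera adjusted p = 0.00165, and 0.101 with an FPKM minimum of 5, fry adjusted p = 0.0176, adjusted p = 0.49 with an estimated correlation). Of 20 endothelial markers 7 rose, with a median of 0.41 and the receptor gene Flt1 at 0.92 (8 adjusted over the list alone; camera adjusted p = 0.00192, fry adjusted p = 0.0872, adjusted p = 0.664 with an estimated correlation). Adventitial fibroblast genes fell in 11 of 20, with Igfbp6 at -1.72 (12 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.000164, fry adjusted p = 0.0119, adjusted p = 0.49 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes fell in 31 of 36, with a median of -0.76 (36 adjusted over the list alone; camera adjusted p = 6e-11, fry adjusted p = 0.0209, adjusted p = 0.496 with an estimated correlation). The median change was -0.28 in the shortest length class of protein-coding genes and 0.19 in the longest. White adipocyte markers were at a median of -0.96, with 5 of 19 that fell and 1 that rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.00332, fry adjusted p = 0.169, adjusted p = 0.725 with an estimated correlation). Heat shock genes fell in 9 of 14 (9 adjusted over the list alone; camera adjusted p = 1.67e-05, fry adjusted p = 0.0176, adjusted p = 0.49 with an estimated correlation). The near-identical Hspa1b and Hspa1a fell by 2.59 and 2.43, and their reads cannot be assigned to either with certainty.

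Cholesterol synthesis genes fell in 9 of 22 and 1 rose, with the enzyme Cyp51 at -0.95 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00139, fry adjusted p = 0.00656, adjusted p = 0.49 with an estimated correlation).

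The 10 largest falls under the naming rule were Retnla, a marker of alternatively activated macrophages (fell by 3.26), Ifi202b (fell by 3.22), G0s2, Pcna-ps2, Hspa1b, Ucp1, Gkn3, Angptl7, Hspa1a and the globin Hbb-bt. Ifi202b, an interferon-inducible gene, was at 8.46 ± 1.30 FPKM in HFD and had 2 reads over the 3 CD libraries and 1 over the 3 HFD_IO libraries. Erythroid genes also fell in HFD_IO against HFD, in 4 of 7 (6 adjusted over the list alone; camera adjusted p = 0.00408, fry adjusted p = 0.0175, adjusted p = 0.49 with an estimated correlation). Hemoglobin took 0.634%, 0.854% and 1.778% of reads in the HFD libraries and 0.199% to 0.317% in HFD_IO, and the source of this RNA was not tested. Of 17 brown fat genes 7 fell, with a median of -0.81 (9 adjusted over the list alone; camera adjusted p = 0.0259, fry adjusted p = 0.0905, adjusted p = 0.722 with an estimated correlation), and camera's adjusted p was 0.0668 without HFD_3, 0.0658 without HFD_IO_1 and 0.111 with an FPKM minimum of 5.

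Leaving out HFD_3, HFD_IO_1 or HFD_IO_2 lowered the count of 3969 genes in HFD_IO against HFD to 2275, 2551 and 2511. With the adipocyte covariate it was 577 and with the skeletal muscle covariate 110, and other splits of the 6 libraries gave 12 to 25 lists by camera, where the real split gave 22, and 0 by fry, where it gave 15.

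**Figure D2:**
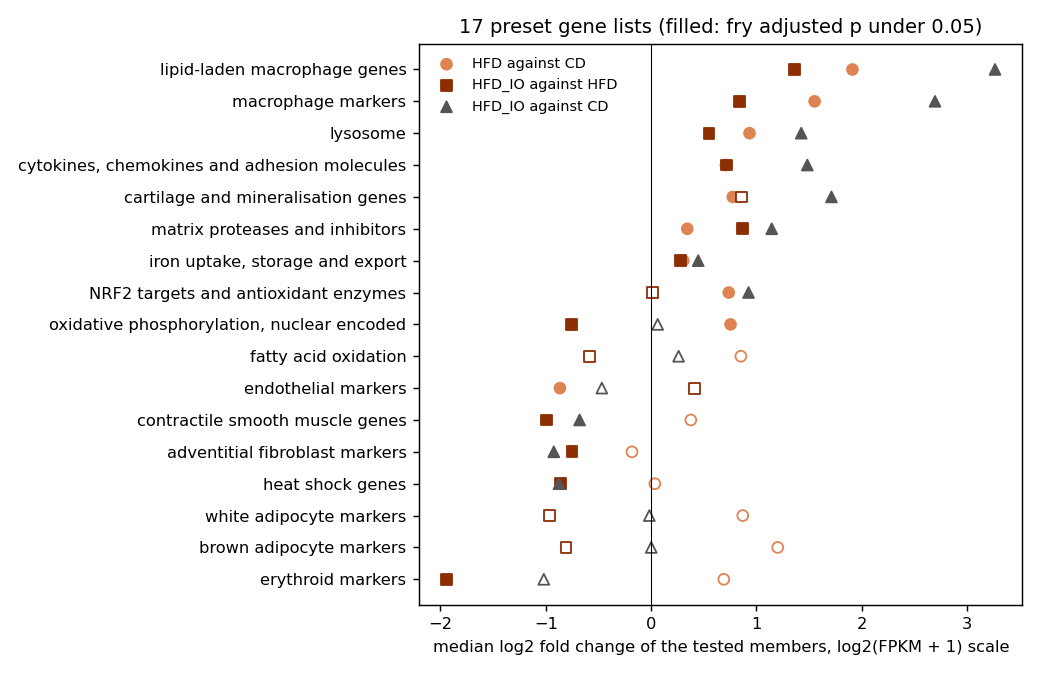
Median log2 fold change of the tested members of 17 preset lists in the 3 comparisons, on the log2(FPKM + 1) scale, filled where fry's adjusted p was under 0.05. Lipid-laden macrophage genes lie at 1.91, 1.36 and 3.265, and contractile smooth muscle genes at 0.38, -0.99 and -0.68.

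The third comparison set iron and diet together against chow. Spp1 was at 3480 ± 1104 FPKM in HFD_IO, a change of 8.13 (SE 0.25, adjusted p = 1.3e-06), and Ibsp, Mmp12, Chad, Npy, Lgals3, Gpnmb, Clec4d, Rnf128 and Adam8 rose by 4.77 to 6.07. The 10 largest falls under the naming rule were Hspa1b, Hspa1a, Actn2, Npas4, Wdr95, Upk3b, Adam33, Klk10 and Nfil3, between -2.23 and -3.35, and the small nucleolar RNA DQ267102, which was listed at 0 in each HFD_IO library. Here 2427 genes rose and 2089 fell, and 47% of genes had groups that did not overlap, where chance gives 10%. Rescaling to TPM moved the median change to -0.23 and left 1528 higher and 3800 lower, and removal of length and GC trends gave 2298 higher and 3398 lower.

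Macrophage markers rose in 20 of 24 with a median of 2.695, among them Cd68 at 4.00 (21 adjusted over the list alone; camera adjusted p = 1.26e-12, fry adjusted p = 7.5e-05, adjusted p = 0.18 with an estimated correlation). Cartilage and mineralisation genes rose in 17 of 22 and 1 fell, with Col2a1, the main collagen of cartilage, at 0.0361 ± 0.0263 FPKM in CD and 34.8 ± 33.5 in HFD_IO (17 and 1 adjusted over the list alone; camera adjusted p = 1.91e-07, fry adjusted p = 0.00101, adjusted p = 0.428 with an estimated correlation). Lcn2 and Cp rose by 3.92 and 0.94, and Tfrc and Gpx4 had adjusted p = 0.391 and 0.994. Fth1 had adjusted p = 0.0586, which was 0.0276 without CD_1, 0.00447 with array weights, 0.0394 with robust eBayes and 0.0351 with an FPKM minimum of 5. Iron genes rose in 13 of 28 and 1 fell, with Ftl1 at 3.06 and Hmox1 at 4.20 (14 and 2 adjusted over the list alone; camera adjusted p = 0.000504, fry adjusted p = 7.98e-05, adjusted p = 0.18 with an estimated correlation). Adventitial fibroblast genes fell in 14 of 20 and 2 rose, with Mfap5 at -1.85 and Lum at 3.05 (15 and 2 adjusted over the list alone; camera adjusted p = 8.39e-05, fry adjusted p = 0.0088, adjusted p = 0.491 with an estimated correlation). The median of the 36 oxidative phosphorylation genes was 0.06 (fry adjusted p = 0.881, camera adjusted p = 0.762). Cdkn2a, a cell cycle inhibitor that marks senescence, rose by 2.75 and Gdf15 by 1.93. Other splits of the 6 libraries gave 8 to 22 lists by camera, where the real split gave 19, and at most 1 by fry, where it gave 17.

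The moderated F test found 7239 genes that differed among the 3 groups. Across the 13883 genes, which are not independent replicates, the diet and iron fold changes had a Pearson r of -0.25 and a Spearman rho of -0.35. Both share the HFD libraries with opposite sign, and 100 simulations of unchanged groups gave r between -0.52 and -0.47 and rho between -0.49 and -0.45. Both observed values lie closer to 0 than in the simulations. The share of genes with the same sign in both comparisons was 34.337%, beside 32.01% to 34.308% in the simulations. The simulated groups hold no real changes, and real changes weaken the r, rho and sign share that the shared group alone gives. These measures therefore cannot say whether opposite movement was commoner than that. The covariance, to which noise of the shared group adds, was -0.081, beside -0.021 in the simulations (-0.022 to -0.019), a difference of -0.06. It was thus more negative than gene-wise noise in the shared group gives. Shifts common to a whole library were not simulated. Of the genes that rose with diet 1090 fell with iron, where independent lists would share 439.3, and 474 rose again, where they would share 426.9. Of the genes that fell with diet 608 rose with iron and 64 fell again, where independent lists would share 343.8 and 353.8. With 3 HFD libraries the shared group cannot be split into parts of 2, so part of the excess of genes that moved in opposite directions, and of the shortfall of genes that fell in both steps, may come from it. The opposite sign lowers the overlap of genes that rose in both steps, so it does not account for that excess. Both comparisons also share each gene's expression level and estimated spread. Calls may therefore coincide more often than in independent lists, and that excess was not tested.

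**Figure D3:**
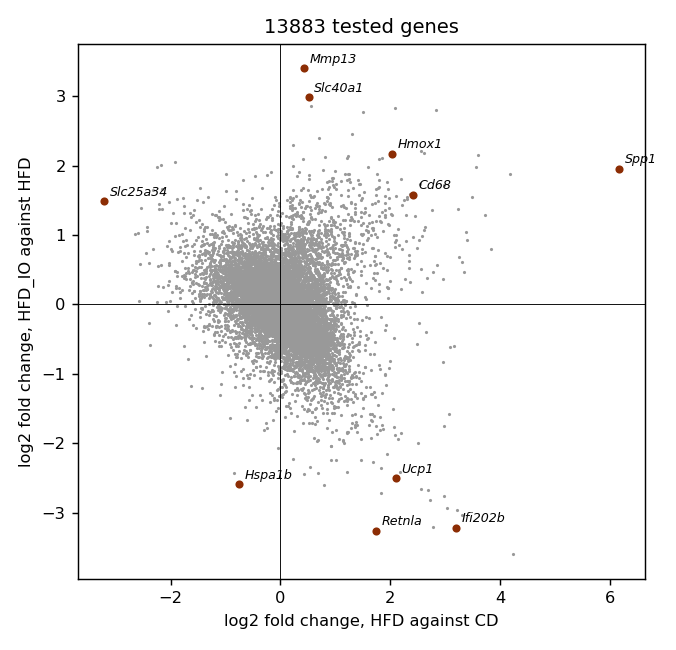
Log2 fold change of HFD against CD (x) and of HFD_IO against HFD (y) for 13883 genes, with 10 genes named. Spp1 rose in both steps (6.17 and 1.96), while Ucp1 rose with the diet and fell with iron (2.10 and -2.50).

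**Figure D4:**
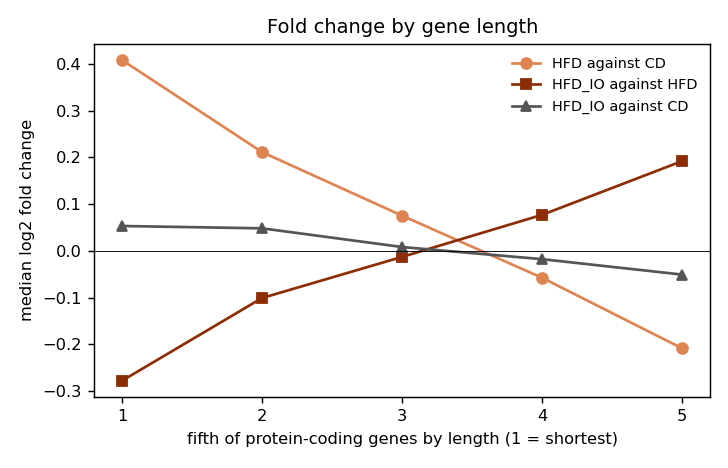
Median log2 fold change of protein-coding genes in 5 equal classes of gene length from shortest to longest, for the 3 comparisons. In HFD against CD it falls from 0.41 in the shortest class to -0.21 in the longest, and in HFD_IO against HFD it rises from -0.28 to 0.19.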

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

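Voom on recovered reads, removal of length and GC trends, protein-coding genes alone omission of both CD_1 and HFD_3, and list tests after a correction, given below, were chosen after seeing the data. No paired analysis was possible because the titles number the aortas 1 to 9 with none shared, and the table's columns could be tied only to groups. The named genes were not rerun with a covariate, a required 2-fold change, voom, trend removal, protein-coding genes alone or omission of both CD_1 and HFD_3. Of 120 gene changes past the threshold and named in the comparisons, 110 kept their call at every setting run on them and 10 lost it in at least 1. They are those of Apoe in HFD_IO against either group, Fth1, Gpx4, Mir1898, Mir23a, Mir3058 and Mir365-1 in HFD against CD, and Tfrc and Gpx4 in HFD_IO against HFD. Each of the 57 list calls lost its call at the estimated correlation, which left 0 lists in each comparison (lowest adjusted p 0.497, 0.218 and 0.107, with 4, 2 and 8 of 42 lists at an unadjusted p under 0.05; fry gave 17, 15 and 17). The genes changed numbered 1071, 781 and 1362 in HFD against CD, HFD_IO against HFD and HFD_IO against CD when a 2-fold change was also required. The adipocyte covariate left 1512 in HFD against CD and 577 in HFD_IO against HFD, and the skeletal muscle covariate 1002 and 110; the cause was not tested. Rescaling to TPM moved the median of all genes to -0.30, 0.14 and -0.23 from 0.06, 0.00 and -0.01, and with it the share of changed genes that were higher to 17.1%, 67.2% and 28.7% from 55.4%, 49.3% and 53.7%. Removal of length and GC trends gave 40.9% higher in HFD against CD and 40.3% in HFD_IO against CD. Under TPM the list medians of ferroptosis and of matrix proteases in HFD against CD turned to -0.017 and -0.033, which lie above the shifted median of all genes. TPM and no filter on low values each gave 25 lists in HFD against CD, beside 16. Voom gave 5588, 4051 and 4619 changed genes, and omission of both CD_1 and HFD_3 gave 5548, 3591 and 5202. CD_1 stood apart from its group on the third principal component. HFD_3 had the highest hemoglobin share and white adipocyte mean of its group. Leaving out 1 library gave 3712 to 6160, 2275 to 3648 and 3045 to 5036 changed genes, 5625 to 8217 in the F test, and 13 to 20, 18 to 24 and 17 to 19 lists. The correlation of diet and iron changes was -0.36 at a pseudocount of 0.01, -0.172 with an FPKM minimum of 5, -0.165 after quantile normalization, and -0.356 to -0.212 without 1 library. The depth of 16660963 to 18308450 reads limits what can be said of genes with few reads, such as Hamp.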

Other observations

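The tests of length bias, of skeletal muscle RNA, of cell shares, of Pcna-ps2 and of strain explanations, and fry after each correction, were chosen only after the results were seen; the fat covariate and the counts of other splits were set before theirs were. Group-restricted expression was searched in all genes of the table, as an FPKM of at least 1 in every library of a group and at least 10 times the highest of the other 6. This gave 4 genes for HFD, 1 for CD (Gm26487, with 7 reads in CD and 0 in the other 6 libraries) and 0 for HFD_IO. Gm26487, Gm3375 and Gm5874 were chosen after their values were seen. The HFD genes were Ifi202b (722 reads in HFD, 2 in CD and 1 in HFD_IO), Gm3375 (1463, 43 and 91), Pcna-ps2 (550, 33 and 33) and Gm5874 (57, 1 and 2). In HFD against CD, 85 of 226 tested long intergenic RNAs fell and 17 rose, and 177 of 631 processed pseudogenes rose and 46 fell, beside 3030 that rose and 2440 that fell of all 13883 genes; no class was tested against the others.

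The oxidative phosphorylation genes were higher in HFD than in CD and lower in HFD_IO than in HFD, with medians of 0.75 and -0.76. Removal of each library's trend on length and GC left a median of 0.46 in HFD against CD (adjusted p = 1.57e-07 by camera; by fry 0.0647, from 0.015), the adipocyte mean as a covariate left 0.337 (1.77e-05 by camera and 0.133 by fry), and the skeletal muscle mean 0.588 (1.28e-06 and 0.232). The mean change of the list went from 0.83 (standard error 0.20) to 0.47 (0.15), 0.40 (0.15) and 0.60 (0.28), so fry's call ended as the change shrank relative to its error, and that trend, RNA from surrounding fat and RNA from skeletal muscle cannot be told apart from a change within the wall. Camera's call carries little weight, since the oxidative phosphorylation call was lost with an estimated correlation (adjusted p = 0.711). Other splits gave up to 22 lists by camera, but each mixes libraries of both groups. Part of the real difference stays in such splits, so that count does not judge the call. In CD, HFD and HFD_IO the most abundant members of the white and brown adipocyte lists were at 503, 989 and 630 FPKM (Cfd) and 148, 493 and 118 (Cox8b). Cox8b and Cox7a1, both in the adipocyte covariate, are themselves genes of oxidative phosphorylation, so part of the decline with that covariate may be built in. Muscle markers disagreed, with Tcap at 87.3, 205 and 154, Acta1 at 1.69, 28.3 and 2.39 and Casq1 at 20.3, 21.6 and 6.75. These levels were chosen after they were seen. The diet stays among the explanations as untested. The fall in HFD_IO against HFD rests on the same HFD libraries, with the length trend and the fat and skeletal muscle medians reversed. No correction of that fall is given here, so it cannot be told apart from that trend or from fat and muscle RNA either.

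The contractile smooth muscle genes fell with iron, with a median of -0.99. A lower share of smooth muscle cells alone would raise the markers of every other cell type, and the endothelial and macrophage medians of 0.414 and 0.838 go with that, but the adventitial fibroblast and white adipocyte medians were -0.751 and -0.961. The fibroblast fall exceeds the standard error of that list's mean (0.137), but this error is over the member genes and does not measure the spread between aortas. Per library, the fibroblast genes averaged 6.248, 5.878 and 6.331 on the log2 scale in HFD and 5.415, 5.592 and 5.582 in HFD_IO (fry adjusted p = 0.0119). These values argue against a lower smooth muscle share as the sole cause. Removal of the length and GC trends left -0.964 (adjusted p = 1.48e-09 by camera and 0.00516 by fry), which argues against that bias. A gain of macrophages beside losses in some other cell types, and lower expression per cell, may both contribute and were not separated.

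The 4 genes that met the 10-fold rule in HFD lie on 4 chromosomes, which argues against a single segment from another strain. Pcna-ps2 was about 12 times or more as large a share of its parent Pcna in every HFD library as in any HFD_IO library, which argues against a fixed share of parent reads spilling to the copy. Unlinked strain or substrain variants in the HFD animals are a candidate explanation for these 4 genes. They cannot be told apart from an effect of the diet reversed by iron, since no genotypes were analysed and any such variants coincide with the group.

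With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 5470 changed genes in HFD against CD and the highest other split 1, in HFD_IO against HFD 3969 and 1, and in HFD_IO against CD 4516 and 0; in each, 1 split reached the real count. For lists by camera, 9, 5 and 6 of the 10 splits gave as many as the real 16, 22 and 19, with highest others of 22, 25 and 22. The other splits mix libraries of both groups and keep part of their difference, so these counts do not weigh camera against fry. Of 280 possible splits of the 9 libraries into 3 groups, 100 were drawn, the real one among them. Only the real one gave as many as 7239 genes in the F test (highest other 1917). Chance assignment of libraries to groups is thus an unlikely source of that count but is not excluded. Here too the other splits mix the groups, which widens the spread within them.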
